A study of Caenorhabditis elegans with 6 samples.

How the data were processed

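RNA was taken from pools of whole worms with a spin-column kit, and stranded mRNA libraries were sequenced on a NovaSeq instrument, per the labels' protocols. The deposited table gives, per gene, raw counts and normalized counts for the 6 libraries. STAR, HTSeq and the genome build WBcel235 are named in the submitters' processing notes; their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of genes that overlap on opposite strands can therefore not be assigned with certainty, and nor can those of overlapping genes on the same strand or of close paralogs. The counts, whole numbers per gene in the authors' deposited table, were the only values tested. The table lists 46926 genes and gives counts for 22407; the 24519 without counts are small or noncoding RNA classes in the annotation. The normalized values, a signal in the authors' deposited table, equal the counts divided by 1 factor per library and are given for the 17746 genes whose 6 counts sum to 10 or more. They were not tested. The count columns of the gtr-1 RNAi libraries are headed with names that start with GT and end with the replicate number, while the labels read GTR1 and the same number, and they were matched on these parts; what the letters OL and ROL in those headers stand for is not stated. Gene names come from the table, which gives none for 2130 of the genes with counts; 1 of these was named from the reference. Coordinates, exons and overlapping genes come from the Ensembl annotation of WBcel235, in which all 22407 gene identifiers were found.

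Total counts ran from 33254426 to 41902475 per library. The 10 most abundant genes, led by the vitellogenin genes vit-2 and vit-6, took 7.40% to 9.97% of counts. The series' design text speaks of 3 sets of worms; the labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The replicate numbers are taken from the titles.

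The comparison was gtr-1 RNAi against EV in all 6 libraries with no covariate. Genes were filtered with edgeR's filterByExpr, which kept 14683 genes, and counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3). The test was the edgeR quasi-likelihood F test with robust estimation, Benjamini-Hochberg adjusted, with a threshold of 0.05. DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives. CPM in the text are TMM-adjusted. Gene lists and families were tested with camera (limma) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and adjustment over the 45 lists with at least 3 tested members or over the 131 families with at least 10. The lists were written from general knowledge of worm tissues and pathways, and they and the tests, the alternatives and the naming rule were fixed before the data were examined. The rule named gtr-1, 6 reporters, the 8 highest and 8 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean log2 CPM over 1 and no overlap in CPM between the groups, and up to 2 called members per list and direction with the smallest p. Because the edgeR test called no gene, the last 2 parts were applied to the DESeq2 calls; that was decided after the edgeR result was seen. DESeq2 leaves some genes without an adjusted p, and they count as not called.

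Other choices tried were DESeq2 size factors or library size alone in edgeR, no filter, a filter of 10 counts in 3 libraries, a threshold of 0.1, a fold of at least 1.5, leaving out the 10 most abundant genes, leaving out each library in turn, the replicate number as a block, estimated correlations, and fry. Added after the data were seen were edgeR without robust estimation, voom with sample quality weights, DESeq2 without each library, and DESeq2 with the replicate block. The fits were tested on simulated counts of 14683 genes, of which 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold. In these, edgeR called 47.8% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 95.5% of those changed 4-fold, with 5 false calls. DESeq2 called 55.2%, 59.7% and 89.4%, with 16 false calls. The simulated genes varied independently of each other, and no simulated library stood away from its group. The real libraries differ in this, so these shares need not hold for them.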

Results

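Gene counts were examined for 6 RNA-seq libraries from pools of whole adult Caenorhabditis elegans of strain AM140. This strain makes a fusion of 35 glutamines and yellow fluorescent protein in body wall muscle from the unc-54 promoter. Worms were fed HT115 bacteria that carried either an empty vector (EV, 3 libraries) or a construct against the 3'UTR of gtr-1 (gtr-1 RNAi, 3 libraries). Parents and progeny received the same bacteria at 20 °C. The parents were bleached on day 1 of adulthood, and generation 2 was cleared of its offspring daily and harvested on day 6. Total counts were 36952416, 39092036 and 33254426 in EV replicates 1, 2 and 3. They were 36392194, 41902475 and 40181943 in gtr-1 RNAi replicates 1, 2 and 3. The design has 1 comparison, gtr-1 RNAi against EV. Per the series title, it addresses how a neuronal G protein-coupled receptor affects neuropeptide signalling and protein homeostasis in distant tissues.

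The targeted transcript was not lower in the libraries labelled gtr-1 RNAi. The gene gtr-1 (WBGene00017779) lies on chromosome X at 802778 to 804269 of WBcel235, on the + strand, with 8 exons and a 3'UTR at 804157 to 804269. Its counts were 16, 25 and 20 in EV replicates 1, 2 and 3. The counts were 20, 24 and 19 in gtr-1 RNAi replicates 1, 2 and 3. Its level was 0.547 ± 0.109 CPM under EV and 0.544 ± 0.0708 CPM under gtr-1 RNAi (mean ± SD, n = 3 each). The edgeR quasi-likelihood test gave a log2 fold change -0.0100 ± 0.28 SE, adjusted p = 0.986. From the summed counts of 61 and 63, the ratio of gtr-1 RNAi to EV was 0.991. Its 95% exact binomial interval, which covers counting error only, was 0.686 to 1.43. RNA from the feeding bacteria may carry the targeted 3'UTR and add to these counts, so they do not settle the level of the worm's own transcript. The libraries are therefore named by their labels, and every direction below is that of the libraries labelled gtr-1 RNAi relative to those labelled EV.

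Of 6 reporter genes, none passed the edgeR test or the DESeq2 test, and limma-voom with sample quality weights called 1, hsp-6, lower (log2 fold change -0.18, adjusted p = 0.00467). The small heat shock gene hsp-16.2 was at 9.75 ± 1.98 CPM under EV and 6.50 ± 1.57 CPM under gtr-1 RNAi (log2 fold change -0.58 ± 0.22 SE, adjusted p = 0.144 by edgeR; log2 fold change -0.39 without gtr-1 RNAi replicate 2). The mitochondrial chaperone gene hsp-6 was at 1400.5 ± 53.3 against 1281 ± 39.0 CPM (log2 fold change -0.13 ± 0.04 SE, adjusted p = 0.121). The endoplasmic reticulum chaperone gene hsp-4 was at 443 ± 13.2 against 428 ± 2.79 CPM (log2 fold change -0.050 ± 0.03 SE, adjusted p = 0.360). The superoxide dismutase gene sod-3, a target of the insulin pathway transcription factor DAF-16, was at 2.92 ± 0.594 against 3.87 ± 0.708 CPM (log2 fold change 0.41 ± 0.20 SE, adjusted p = 0.230; log2 fold change 0.25 without gtr-1 RNAi replicate 2). Exons of other genes lie on its opposite strand. The myosin gene unc-54, whose promoter drives the transgene, was at 545 ± 153 against 660.3 ± 81.8 CPM (log2 fold change 0.28 ± 0.23 SE, adjusted p = 0.475). Its log2 fold change was 0.077 without EV replicate 3, 0.48 without EV replicate 2 and 0.18 without gtr-1 RNAi replicate 1. The chaperone gene hsp-70 was at 47.4 ± 3.83 against 46.7 ± 4.54 CPM (log2 fold change -0.022 ± 0.08 SE, adjusted p = 0.885).

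**Figure D1:**
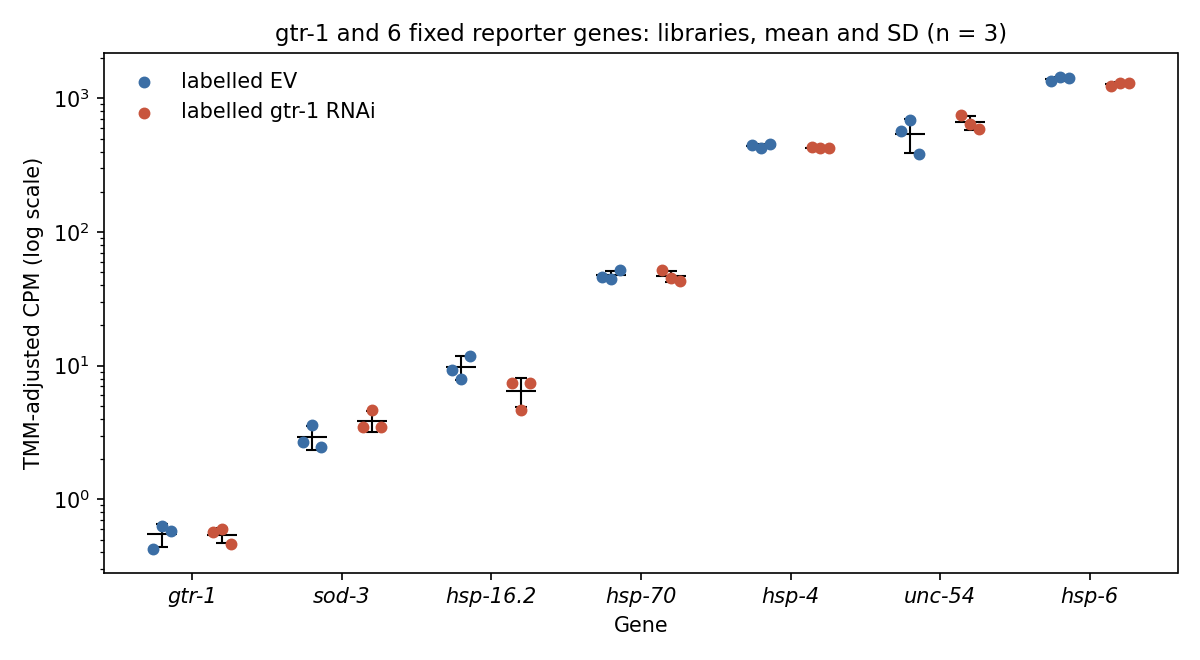
Points are TMM-adjusted CPM (log axis) of gtr-1 and 6 reporter genes in each library labelled EV (blue) or gtr-1 RNAi (red), with the mean (horizontal tick) and SD (bars, n = 3). The gtr-1 means are 0.547 and 0.544 CPM, and the hsp-16.2 means 9.75 and 6.50 CPM.

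Among single genes, DESeq2 called the diacylglycerol acyltransferase gene dgat-2 higher in the libraries labelled gtr-1 RNAi, at 14.8 ± 2.82 CPM under EV and 32.2 ± 9.95 CPM under gtr-1 RNAi (log2 fold change 1.13 ± 0.21 SE, adjusted p = 1.94e-05). Also higher by DESeq2 were the enoyl-CoA hydratase gene ech-7 (1.26 ± 0.19, adjusted p = 3.76e-07) and the glutathione peroxidase gene gpx-5 (0.95 ± 0.16, adjusted p = 4.73e-06). The saposin-like gene spp-17 (0.75 ± 0.16, adjusted p = 0.000441) and the UDP-glucuronosyltransferase gene ugt-46 (1.26 ± 0.23, adjusted p = 1.55e-05) were higher too. Lower by DESeq2 were the ankyrin gene unc-44 (log2 fold change -0.58 ± 0.10 SE, adjusted p = 1.43e-05) and the troponin I gene tni-1 (-0.61 ± 0.14, adjusted p = 0.000665). The fatty acid desaturase gene fat-3 (-0.51 ± 0.11, adjusted p = 0.000341) and the transhydrogenase gene nnt-1 (-0.76 ± 0.16, adjusted p = 0.000258) were lower as well. The naming rule was moved to DESeq2 calls after edgeR had called no gene. These 9 belong to 19 of the 123 genes chosen by that rule and called by DESeq2 that DESeq2 also called with any 1 library left out. Of the others, it called 17 in only 1 of these 6 fits, 33 in 2, 19 in 3, 17 in 4 and 18 in 5. Among the genes named below, vha-6, asp-12, ugt-57, nlp-59, ins-34, unc-31, hid-1 and cnd-1 were called in only 1 of these fits, that without gtr-1 RNAi replicate 3. Exons of other genes overlap unc-44 on both strands and dgat-2 and nnt-1 on the opposite strand, so part of their counts is uncertain. Genes named below with such overlaps on the opposite strand include ugt-57, lea-1, ins-34 and kpc-1.

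The same rule, moved from edgeR to DESeq2 after the edgeR result was seen, also picked the widest fold changes. They were taken among DESeq2 calls with a mean log2 CPM over 1 and no overlap in CPM between the groups. Of these, the highest was that of Y48E1B.8 (WBGene00013007, chromosome II, 13585705 to 13589038), at 1.34 ± 1.31 CPM under EV and 15.5 ± 8.82 CPM under gtr-1 RNAi (log2 fold change 3.55 ± 0.96 SE, adjusted p = 0.00508). It was followed by the folate transporter gene folt-2 (2.93 ± 1.02, adjusted p = 0.0360), the cuticle collagen gene col-160 (2.47 ± 0.62, adjusted p = 0.00233) and the neprilysin family gene nep-8 (2.46 ± 0.44, adjusted p = 1.43e-05). The lowest was that of the cyclophilin gene cyn-17 (WBGene00000893, chromosome V, 5799673 to 5805666), at 4.24 ± 0.726 CPM under EV and 1.10 ± 1.08 CPM under gtr-1 RNAi (log2 fold change -1.94 ± 0.50 SE, adjusted p = 0.00358). T26C5.2 (-1.85 ± 0.49, adjusted p = 0.00428) came next, and the lipase gene lipl-3 (-1.74 ± 0.43, adjusted p = 0.00208) and bro-1 (-1.71 ± 0.47, adjusted p = 0.00560) were also among the 8 lowest. Counts of col-160 and lipl-3 are uncertain because exons of col-159 and srw-107 overlap them on the same strand, and Y48E1B.8 has an antisense neighbour. By edgeR, the log2 fold changes without gtr-1 RNAi replicate 3 were -3.14 for cyn-17 and -2.99 for T26C5.2, against -1.93 and -1.85 with 6 libraries. That of folt-2 was 4.49 without EV replicate 1, against 2.91. Of the 8 highest and 8 lowest genes, DESeq2 called 1 without gtr-1 RNAi replicate 1, 2 without gtr-1 RNAi replicate 2, 3 without EV replicate 2 and 5 without EV replicate 3. It called 13 without EV replicate 1 and 16 without gtr-1 RNAi replicate 3.

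By the edgeR quasi-likelihood test, the one fixed for this comparison, 0 genes were higher and 0 lower at an adjusted p under 0.05 among 14683 genes. The smallest adjusted p was 0.112. At an unadjusted p under 0.05, edgeR gave 1898 higher and 2242 lower genes. With the replicate number as a block, it called 467 higher and 492 lower at an adjusted p under 0.05, though the labels do not say that the numbers pair samples. The DESeq2 Wald test called 853 higher and 971 lower genes, and limma-voom called 0, or 2359 higher and 3178 lower with sample quality weights. Of the genes tested by edgeR, 36.2% had no overlap in CPM between the groups, where chance gives 10% for a single gene. Genes varied together across the libraries, so 1 ordering of the libraries can move this share far from 10%. The share was not tested. The counts moved with the library left out. Without gtr-1 RNAi replicate 3, edgeR called 1308 higher and 2236 lower genes, and DESeq2 1552 and 1997. DESeq2 called 99 and 49 without gtr-1 RNAi replicate 1, and 206 and 191 without gtr-1 RNAi replicate 2. It called 776 and 692 without EV replicate 1, 318 and 225 without EV replicate 2, and 190 and 93 without EV replicate 3.

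The libraries were ordered by label on the first principal component, but the 2 nearest libraries carried different labels. On log2 CPM, component 1 held 72.7% of the variance. It placed gtr-1 RNAi replicate 3 at -6.62 and gtr-1 RNAi replicates 1 and 2 at 41.8 and 59.9. EV replicates 1, 2 and 3 lay at -19.2, -35.3 and -40.6. The smallest distance of any pair of libraries, a root mean square difference of 0.272 log2 CPM over genes, was that between EV replicate 1 and gtr-1 RNAi replicate 3. No pair agreed within sampling noise (smallest chi-square per degree of freedom 5.18), so no libraries were merged, which does not show that they came from separate cultures.

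**Figure D2:**
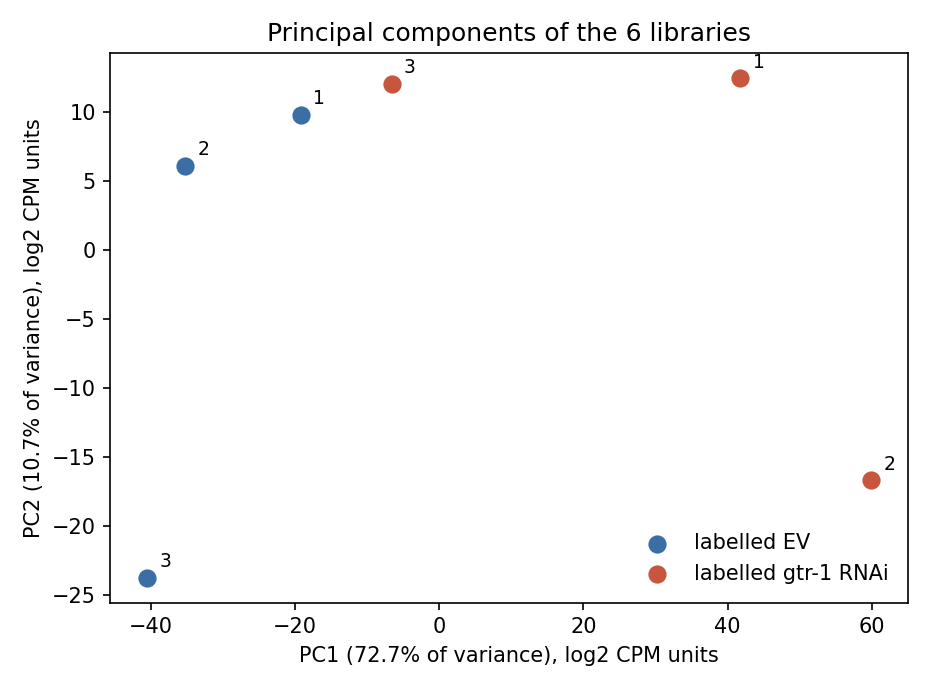
Points are the 6 libraries labelled EV (blue) or gtr-1 RNAi (red) with their replicate numbers, on principal components 1 and 2 of log2 CPM (72.7% and 10.7% of the variance). On component 1, gtr-1 RNAi replicate 3 lies at -6.62, nearer to EV replicate 1 (-19.2) than to gtr-1 RNAi replicate 1 (41.8).

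The set test assumes a correlation of 0.01 between genes. The estimated correlations were 0.376 for the lysosomal list, 0.704 for the mitochondrial genome genes and 0.905 for the vitellogenins. Its adjusted p can therefore be too small, so calls are given with that from the estimated correlation. Of 10 splits of the libraries into 3 and 3, the labelled one included, 5 gave at least 14 lists. Lysosomal genes and vacuolar ATPase subunits rose as a group by the set test (median log2 fold change 0.22, set test adjusted p = 2.83e-06, and adjusted p = 0.831 with an estimated correlation). DESeq2 called 20 of 47 members higher, among them the cathepsin gene cpz-1 (0.48 ± 0.11, adjusted p = 0.000489) and the intestinal ATPase gene vha-6 (0.62 ± 0.14, adjusted p = 0.000864). It called 1 lower, the aspartyl protease gene asp-12 (-0.65 ± 0.20, adjusted p = 0.0155). Genes of the mitochondrial genome rose as a group (median log2 fold change 0.23, set test adjusted p = 0.00198; adjusted p = 0.831 with an estimated correlation). DESeq2 called 8 of 10 higher, including the cytochrome oxidase gene ctc-3 (0.22 ± 0.05, adjusted p = 0.00142). Intestine genes rose as a group (median log2 fold change 0.24, set test adjusted p = 0.0153; adjusted p = 0.831 with an estimated correlation). DESeq2 called 8 of 19 higher, such as the intermediate filament gene ifc-2 (0.48 ± 0.10, adjusted p = 0.000531), and 1 lower, eps-8 (-0.36 ± 0.09, adjusted p = 0.00195). Of these 19 genes, 7 also belong to other lists tested, vha-6 among them. With p adjusted over the list alone, edgeR called 23 up and 2 down of the lysosomal genes, 7 up and 0 down of the mitochondrial genome genes and 7 up and 1 down of the intestine genes, and 0 with p adjusted over all genes tested. In gtr-1 RNAi replicate 3 the centred medians of these lists were -0.024, -0.047 and -0.044, below those of gtr-1 RNAi replicates 1 and 2. Without EV replicate 3 the call of the intestine genes was lost (set test adjusted p = 0.0765).

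Vitellogenin genes, which encode yolk proteins made in the intestine, rose as a group (median log2 fold change 0.60, set test adjusted p = 0.00891; adjusted p = 0.831 with an estimated correlation). DESeq2 called 3 of 6 higher, including vit-1 at 427 ± 179 against 1016 ± 264 CPM (1.26 ± 0.41, adjusted p = 0.0239), and reads could be split between these similar genes. UDP-glucuronosyltransferases rose as a group (median log2 fold change 0.20, set test adjusted p = 0.00668; adjusted p = 0.831 with an estimated correlation). DESeq2 called 17 of 61 higher, such as ugt-19 (1.14 ± 0.22, adjusted p = 7.22e-05), and 1 lower, ugt-57 (-1.31 ± 0.47, adjusted p = 0.0414; by edgeR -1.32, and -2.08 without gtr-1 RNAi replicate 3). Glutathione S-transferases rose as a group (median log2 fold change 0.15, set test adjusted p = 0.0153; adjusted p = 0.831 with an estimated correlation). DESeq2 called 12 of 40 higher, such as gst-26 (1.35 ± 0.31, adjusted p = 0.000826), and 2 lower, such as gst-15 (-0.99 ± 0.27, adjusted p = 0.00630). Genes repressed by DAF-16, a list that also holds vit-2 and vit-5, rose as a group (median log2 fold change 0.42, set test adjusted p = 0.0117; adjusted p = 0.831 with an estimated correlation). DESeq2 called 3 of 9 higher, such as dod-17 (1.47 ± 0.37, adjusted p = 0.00264) and dod-19 (1.15 ± 0.36, adjusted p = 0.0180). With the 10 most abundant genes left out, 3 of them the vitellogenin genes vit-2, vit-5 and vit-6, the median of the vitellogenins was 1.25 (set test adjusted p = 0.0424). With p adjusted over the list alone, edgeR called 0 up and 0 down of the vitellogenins, 2 up and 0 down of the UDP-glucuronosyltransferases, 6 up and 1 down of the glutathione S-transferases and 1 up and 0 down of the genes repressed by DAF-16. The centred median of the vitellogenins was -0.78 in EV replicate 3, against -0.10 and -0.077 in EV replicates 1 and 2. Without EV replicate 3 the set test lost the calls of glutathione S-transferases (adjusted p = 0.0924) and genes repressed by DAF-16 (adjusted p = 0.0644). The median of the glutathione S-transferases was 0.27 without gtr-1 RNAi replicate 2, 0.26 without gtr-1 RNAi replicate 3 and 0.092 with library size in place of TMM.

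Germline and oocyte genes rose as a group by a small amount (median log2 fold change 0.085, set test adjusted p = 0.00198; adjusted p = 0.831 with an estimated correlation). DESeq2 called 7 of 48 higher, including the maternal RNA-binding protein genes spn-4 (0.36 ± 0.07, adjusted p = 0.000160) and pos-1 (0.26 ± 0.06, adjusted p = 0.00170), and 1 lower, fbf-2 (-0.29 ± 0.08, adjusted p = 0.00980). The median was 0.13 without gtr-1 RNAi replicate 3 and 0.026 with library size in place of TMM. With p adjusted over the list alone, edgeR called 6 up and 1 down of these genes. Proteasome subunits rose as a group by less (median log2 fold change 0.037, set test adjusted p = 0.0433; adjusted p = 0.859 with an estimated correlation), and with library size in place of TMM their median turned to -0.021. DESeq2 called 0 of 33 subunits, as did edgeR with p adjusted over the list alone. The set test lost this call with library size (adjusted p = 0.674). It was also lost without EV replicate 2 (adjusted p = 0.107), EV replicate 3 (0.0556), gtr-1 RNAi replicate 1 (0.0708) or gtr-1 RNAi replicate 2 (0.12).

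Pan-neuronal genes fell as a group by the set test (median log2 fold change -0.22, set test adjusted p = 0.00668; adjusted p = 0.831 with an estimated correlation). Of 17 genes, 16 had negative fold changes and 2 were lower by DESeq2, unc-44 and the synaptic vesicle priming gene unc-13 (-0.46 ± 0.13, adjusted p = 0.00591). At its overall rate DESeq2 would call 1.12 of this list lower. Genes induced by DAF-16 fell as a group (median log2 fold change -0.49, set test adjusted p = 0.00891; adjusted p = 0.831 with an estimated correlation). DESeq2 called 7 of 16 lower, among them nnt-1 and lea-1 (-0.46 ± 0.09, adjusted p = 3.87e-05). Hedgehog-related and patched-related genes fell as a group (median log2 fold change -0.52, set test adjusted p = 0.00891; adjusted p = 0.831 with an estimated correlation). DESeq2 called 13 of 61 lower, such as ptr-18 (-1.30 ± 0.32, adjusted p = 0.00180), and 4 higher, such as grd-14 (1.31 ± 0.29, adjusted p = 0.000688). Autophagy genes fell as a group (median log2 fold change -0.11, set test adjusted p = 0.0155; adjusted p = 0.831 with an estimated correlation). DESeq2 called 9 of 28 lower, including the receptor gene sqst-1 (-0.36 ± 0.09, adjusted p = 0.00166), and 1 higher, epg-4 (0.20 ± 0.06, adjusted p = 0.0143). F-box, SKP1-related and cullin genes fell as a group (median log2 fold change -0.17, set test adjusted p = 0.0242; adjusted p = 0.831 with an estimated correlation). DESeq2 called 19 of 274 lower, such as fbxc-40 (-1.29 ± 0.28, adjusted p = 0.000349), and 9 higher, such as fbxa-215 (0.31 ± 0.07, adjusted p = 0.00116). At its overall rate DESeq2 would call 18.1 of the list lower, and the largest F-box family, fbxa, was not called (median 0.0062, 64 members positive and 55 negative, set test adjusted p = 0.475). With p adjusted over the list alone, edgeR called 1 up and 9 down of the genes induced by DAF-16, 2 up and 10 down of the autophagy genes and 0 up and 2 down of the pan-neuronal genes. It called 0 up and 0 down of the hedgehog-related and patched-related genes and 0 up and 0 down of the F-box, SKP1-related and cullin genes. Autophagy genes lost the call without EV replicate 3 (set test adjusted p = 0.0765) or gtr-1 RNAi replicate 1 (0.0618), and their median was -0.17 with library size in place of TMM. F-box, SKP1-related and cullin genes lost it without EV replicate 3 (0.172), with library size (0.110) and with no filter (0.0660). In gtr-1 RNAi replicate 3 the centred medians of the pan-neuronal, DAF-16-induced and autophagy lists were 0.021, -0.021 and -0.0059, above those of gtr-1 RNAi replicates 1 and 2.

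**Figure D3:**
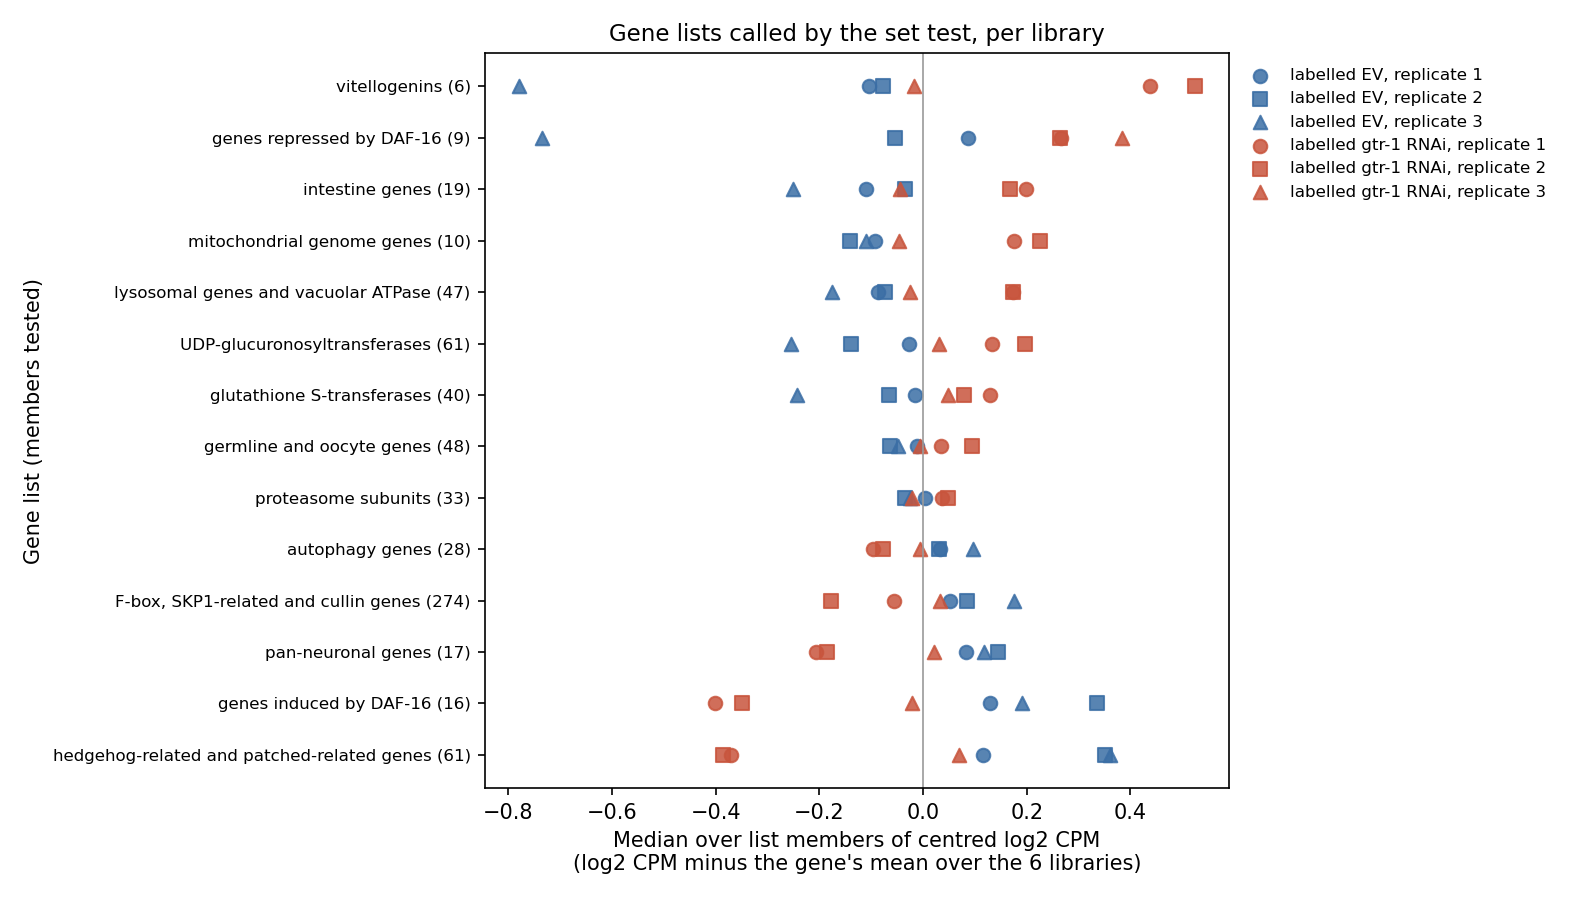
Each row is a gene list called by the set test (number of members tested), and each point the median over its members of log2 CPM minus the gene's mean over the 6 libraries, for libraries labelled EV (blue) or gtr-1 RNAi (red). For the hedgehog-related and patched-related genes, gtr-1 RNAi replicate 3 lies at 0.069, against -0.37 and -0.39 for replicates 1 and 2.

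FMRFamide-like peptide genes, a neuropeptide class, were not called as a group (set test adjusted p = 0.148, median log2 fold change 0.11), and DESeq2 called 0 of 30. Neuropeptide-like protein genes were not called as a group either (adjusted p = 0.203). Of 64 such genes, DESeq2 called nlp-59 (0.75 ± 0.22, adjusted p = 0.0109) and nlp-77 (0.45 ± 0.11, adjusted p = 0.00210) higher and nlp-39 (-0.42 ± 0.14, adjusted p = 0.0252) lower. Of 21 insulin-like peptide genes, it called ins-34 lower (-0.84 ± 0.29, adjusted p = 0.0373). By edgeR its log2 fold change was -0.84, -0.55 without gtr-1 RNAi replicate 2 and -1.29 without gtr-1 RNAi replicate 3. Of 16 genes of neuropeptide processing and dense core vesicles, DESeq2 called 3 lower. They were the proprotein convertase gene kpc-1 (-0.61 ± 0.15, adjusted p = 0.00218), unc-31 (-0.48 ± 0.17, adjusted p = 0.0355) and hid-1 (-0.34 ± 0.12, adjusted p = 0.0353). That list was not called as a group (set test adjusted p = 0.827, median log2 fold change 0.024), and 9 of its members had positive fold changes. Of 101 peptide and amine receptor genes, DESeq2 called the receptor gene pdfr-1 higher (0.38 ± 0.10, adjusted p = 0.00280). At its overall rate DESeq2 would call 5.87 of these receptor genes higher and 6.68 lower. It would call 3.72 neuropeptide-like protein genes higher and 4.23 lower, and 1.39 insulin-like peptide genes lower. The calls in these lists do not exceed that rate. For the processing list the rate gives 1.06 lower, against 3 called.

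Small heat shock protein genes missed the set test's threshold (adjusted p = 0.0511, median log2 fold change -0.58, 11 genes), and passed it without gtr-1 RNAi replicate 3 (adjusted p = 0.0444). DESeq2 called hsp-12.6 lower (-1.64 ± 0.44, adjusted p = 0.00471) and hsp-17 higher (1.44 ± 0.37, adjusted p = 0.00316). At its overall rate DESeq2 would call 0.727 of this list lower and 0.639 higher. Cytosolic chaperones and the HSF-1 pathway (21 genes, set test adjusted p = 0.183) had 0 members called by DESeq2. Chaperonin and prefoldin genes (14 genes, set test adjusted p = 0.502) had 0 as well. Endoplasmic reticulum chaperone genes (22 genes, set test adjusted p = 0.12) had 2 lower members by DESeq2, pdi-2 (-0.23 ± 0.06, adjusted p = 0.00825) and enpl-1 (-0.17 ± 0.05, adjusted p = 0.0174). The overall rate gives 1.45 lower for this list. Of 36 body wall muscle genes, 5 were lower by DESeq2, including tni-1. The median of this list was 0.073 and the set test gave adjusted p = 0.997. Cuticle collagens were not called as a group (set test adjusted p = 0.497, median 0.22). Of 134 collagen genes, DESeq2 called 25 higher and 6 lower. Of the 139 tested without gtr-1 RNAi replicate 3, edgeR called 13 higher and 39 lower. In all, the set test called 9 of 45 lists higher and 5 lower, and 0 with an estimated correlation.

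Families of genes that share a symbol prefix were tested as well. Of those named here, fbxb is part of the F-box list and vha part of the lysosomal list, so their calls are not separate support. F-box genes of the fbxb family fell (82 of 96 negative, median log2 fold change -0.50, set test adjusted p = 4.21e-07). Cuticlin-like genes, cutl, fell (22 of 24 negative, median -0.86, set test adjusted p = 3.53e-05). The transcription factor families hlh (median -0.62, 10 of 12 negative, adjusted p = 0.0310) and ceh (median -0.21, 36 of 51, adjusted p = 0.0389) fell too. The vacuolar ATPase family vha rose (20 of 20 positive, median 0.20, set test adjusted p = 3.28e-05), as did nspc (14 of 14, median 0.62, adjusted p = 0.000268). In all, 8 of 131 families were called higher and 12 lower. With an estimated correlation 0 were called, at adjusted p = 0.901 for each family named here. With library size in place of TMM no called family changed direction, and the calls of hlh (set test adjusted p = 0.0574) and ceh (0.0567) were lost. Those of nhr (0.0533), gcy, dpy and egl (0.0567 each) and dyf (0.103) were lost too. All the families lost were called lower. The calls of hlh and ceh were lost without EV replicate 2 as well (adjusted p = 0.0679 each). That of ceh was also lost without EV replicate 3 (adjusted p = 0.0513) or gtr-1 RNAi replicate 2 (adjusted p = 0.0885, median -0.13). Without gtr-1 RNAi replicate 2 the median of fbxb was -0.31.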

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

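Voom with sample quality weights, edgeR without robust estimation and all DESeq2 fits with a library left out or a block were chosen after the data were seen. The counts of 0 higher and 0 lower genes by edgeR kept their value with DESeq2 size factors, library size alone, no filter, the stricter filter, a threshold of 0.1, a fold of 1.5, the 10 most abundant genes left out, limma-voom and edgeR without robust estimation. Because the smallest adjusted p by edgeR was 0.112, the threshold of 0.1 and the fold of 1.5 could give no other counts. The counts became 853 and 971 with DESeq2 and 2359 and 3178 with voom and sample quality weights. Leaving out 1 library at a time gave 0 to 1308 higher and 0 to 2236 lower genes by edgeR, above 0 only without gtr-1 RNAi replicate 3, and 99 to 1552 higher and 49 to 1997 lower by DESeq2, which called 736 and 934 with the replicate block. The cause was not tested.

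Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered libraries from their group means correlated at 0.240, -0.107 and 0.197 across genes, and 4 of 6 libraries correlated best with their own number. With 3 libraries per group these values cannot decide it. The replicate block gave 467 higher and 492 lower genes by edgeR. With the block, the set test called 16 lists, 13 of them among the 14: it lost the proteasome subunits (adjusted p = 0.0814) and gained, among others, the small heat shock proteins (0.0362).

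The 14 lists and 20 families became 0 and 0 with an estimated correlation, and the lists 0 with fry, whose test does not compare a list with other genes. Leaving out 1 library gave 9 to 18 lists and 14 to 20 families; the other settings gave 14 to 20 lists and 17 to 22 families. The called lists kept the direction of the set test in all 182 tests under other settings, and 14 of these lost the call; the median of the proteasome subunits alone changed sign, to -0.021 with library size. The log2 fold change of gtr-1 was 0.0029 with DESeq2 and -0.16 to 0.12 with 1 library left out, and that of hsp-70 was 0.13 with voom and sample quality weights and -0.10 to 0.046 with 1 library left out, none past the threshold. The deposited table holds no comparison by the authors, so that alternative was not run. At this depth the 95% interval for the ratio of gtr-1 counts, which covers counting error only, reaches down to 0.686. RNA from the feeding bacteria may add to the counts, so this interval does not exclude a lower level of the worm's own transcript.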

Other observations

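The tests of replicate 3, the lists of developmental genes and the test on fewer larvae were chosen after the result was seen, as were the count of edgeR splits, the standard error in the length test, the comparison of replicate 3 with the places of the EV libraries, and the requirement that members go one way. Developmental regulators of neuroblasts and body regions, among them the neurogenic gene cnd-1 (-1.23 ± 0.45, adjusted p = 0.0472 by DESeq2; by edgeR -1.22, and -1.99 without gtr-1 RNAi replicate 3), had negative fold changes in 25 of 26 genes (median log2 fold change -0.66 by edgeR), and DESeq2 called 8 of them lower and 0 higher. Because the list of developmental regulators was chosen after the result was seen, its shared direction describes the genes chosen and is no test. Moulting genes had a median of -0.65 over 18 genes, of which DESeq2 called 5 lower and 1 higher. Furrow and other moult-cycle collagens had a median of -0.17 over 16 genes, with 0 called lower and 1 higher, and the 134 cuticle collagens of the planned list had a median of 0.22, with 6 called lower and 25 higher.

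The first pattern is the place of gtr-1 RNAi replicate 3 with the EV libraries. An exchange of its label with EV replicate 1 is argued against by the distance of EV replicate 1 to gtr-1 RNAi replicates 1 and 2, at least 0.569 log2 CPM, which exceeds its distance to the other EV libraries, at most 0.387. Its total of 40181943 counts lies within the range of the other 5 libraries, which argues against depth. On the axis from the EV mean (0) to the mean of gtr-1 RNAi replicates 1 and 2 (1), it lies at 0.308, while EV replicates 1, 2 and 3 lie at 0.240, -0.00637 and -0.0722 from the mean of the other 2, so a single wrong label or a mixture with EV material may account for it and cannot be told apart from a weaker response in that sample, which was not tested.

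The second pattern is the negative median of moulting genes, moult-cycle collagens and developmental regulators. Members of the moulting and collagen lists went both ways, so neither list is shown to be lower. The developmental regulators mostly went one way, but that list was chosen after the result was seen. Unequal counting of short and long transcripts was tested as a source of the pattern only for moulting genes and moult-cycle collagens. That test cannot decide, because their members went both ways. Their median was -0.48 and stayed at -0.47 on the log2 scale (standard error 0.277) relative to genes of the same exon length. Medians of the 20 length classes ran only from -0.055 to 0.067, so genes in general moved little with length. Fewer larvae or late embryos in the preparations labelled gtr-1 RNAi are a candidate explanation, although offspring were removed daily: without gtr-1 RNAi replicate 3 the medians were -0.89 for moulting genes, -0.36 for moult-cycle collagens and -0.97 for developmental regulators. But 11 of 18 moulting genes and 9 of 17 collagens were negative, and the planned list of embryonic genes was not called (median -0.058, 23 of 41 negative, set test adjusted p = 0.416), so it cannot be told apart from a change within the adults, and an effect of the RNAi treatment stays open too. The bound first written for larvae was met, and the requirement that members go one way, added once the values were seen, left that test undecided. The length test passed the bound of 0.1 written for it. With 19 of 34 members negative, it is undecided under the same requirement.

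The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1824 genes by DESeq2, the most of the 10 (1 of 10 as large), and the highest other gave 34. By edgeR, all 10 splits gave 0 genes, the highest other among them. For gene lists, 5 of 10 splits gave as many as the real 14, and the highest other gave 19. For families, 2 of 10 gave as many as the real 20, and the highest other gave 20. The numbers of lists and families called therefore do not set the labelled grouping apart from other splits.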
